A study of Arabidopsis thaliana with 12 samples.

How the data were processed

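Total RNA of Arabidopsis thaliana was measured on 12 single-colour arrays, 6 of WT and 6 of the psah2 mutant. Groups and replicate numbers were taken from the sample titles. The authors deposited a table of 3439 probes with 1 intensity per array on a linear scale, which ends at 100 and is never below 0. How these intensities were background-corrected and scaled, and the scanner or imager used, is not given in the sources used here. No column lay outside the 12 samples.

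The array columns did not share a median or a sum within 5%, so, by a rule fixed before the data were examined, values were log2-transformed, values at 0 were left missing, and arrays were quantile-normalized. A probe was tested with at least 4 values in each group, which left 796 probes untested. This leaves out probes at 0 in either group, and quantile normalization removes any true difference in total signal between the groups. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05, with no covariate. Fold changes are on the normalized log2 scale, and intensities in the text are the deposited ones, with SD over the arrays of a group.

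Probes were named only from the platform annotation and a table of RefSeq genes of assembly TAIR10.1. Of the 3439 probes, 692 had 1 gene, 870 several and 1877 none listed. Of the 692, 690 matched a locus, and 523 of these were tested. Probes with several genes were not named. No coordinates are given, since the build behind the probes is not given in the sources used here. The annotation was not checked against probe sequences. In 47 cases 2 tested probes were annotated with the same genes, 46 of them with several genes, and the levels of such probes correlated with only r = 0.089, so the names rest on the annotation alone.

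Before the data were examined, 19 gene lists with 313 genes were fixed. Only 18 of these genes had a 1-gene probe and 13 were tested, so no list reached the minimum of 5 tested members. The 8 lists of photosynthesis, photorespiration and chlorophyll synthesis were then merged, and lists of fibrillins, mTERF proteins, pentatricopeptide repeat proteins, redox proteins and NDH complex genes were added after the data were seen. Lists were tested with camera (correlation preset at 0.01) on the moderated statistics, with camera at an estimated correlation and with fry on probes without missing values. A gene with several probes counted by its brightest. The named genes are the 10 largest rises and the 10 largest falls among called 1-gene probes, and of each list up to 4 called members or, where none was called, the 2 of smallest p. Members beyond these were named after their values were seen.

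The fit was tested on simulated data with the means and spreads of the 2643 tested probes and 200 changed ones. It recovered 22% of the 1.5-fold, 60% of the 2-fold, 76% of the 4-fold and 96% of the 8-fold changes, and called 13 of 2443 unchanged probes. The simulated noise was independent between arrays and was drawn after normalization. In the data, consecutive arrays resembled each other and 1625 probes were called, so these rates may not hold there. In the same simulation 7% of 1000 random lists of 8 probes passed camera at an unadjusted 0.05. Alternatives were other normalizations, filters, floors, averaged consecutive replicates, other priors, array weights, a fold threshold and each array left out. The replicate number was also used as a block, as a fixed term unless a random one is named. Whether the replicate numbers pair the samples was checked by correlating the deviations from the group means.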

Results

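The transcriptome of the Arabidopsis thaliana mutant psah2, described by its submitters as lacking the photosystem I protein PSI-H2, was compared with that of the wild type (WT), both in the Columbia 0 background. PSI-H2 is a small subunit of photosystem I, the complex that passes electrons from plastocyanin to ferredoxin in the thylakoid membrane. Total RNA of 6 WT and 6 psah2 samples was measured on single-colour arrays of 3439 probes. The tissue, age and growth conditions of the plants were not given in the sources used here. The labels do not say whether the 6 samples of a group came from separate plants, so p-values measure the spread between these samples, which may be technical. Precision is limited by the number of arrays.

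The 2 groups of arrays differed in overall brightness. The median deposited intensity, on a scale that ends at 100, was 0.339 ± 0.033 in WT and 0.0946 ± 0.0037 in psah2 (SD, n = 6 each). On average 13.5% ± 0.3 of the probes were listed at 0 in WT and 21.3% ± 1.0 in psah2 (SD, n = 6 each). At the bright end, 5 probes stood at the top of the scale on all 6 psah2 arrays, where their level is only a lower bound. The WT arrays gave these 5 probes intensities from 56.5 to 100. After quantile normalization, log2 intensities correlated across probes with a median r of 0.95 between WT arrays, 0.83 between psah2 arrays and 0.71 between a WT and a psah2 array.

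**Figure D1:**
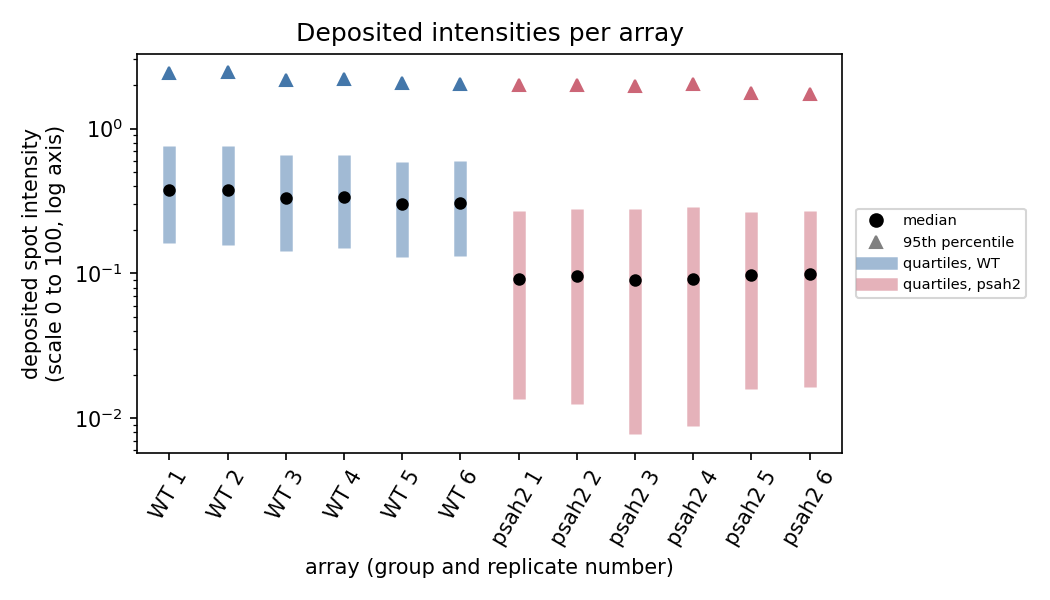
Deposited spot intensity (log axis, scale 0 to 100) of all 3439 probes on each of the 6 WT and 6 psah2 arrays; points are medians, bars span the quartiles and triangles mark the 95th percentile. The medians lie between 0.304 and 0.379 in WT and between 0.0904 and 0.0995 in psah2.

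The question of the design was which transcripts differ in plants that lack PSI-H2. The gene named by the mutant was to be given first as a check of the labels. No probe was paired with PSAH2, or with its near-identical copy PSAH1, in the annotation used here, so the level of neither transcript was analysed here and the labels were not checked by it.

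Of 125 listed genes of photosynthesis, photorespiration and chlorophyll synthesis, only 8 could be tested. Of these 8, 6 rose in psah2, 1 fell and 1 did not pass the test, while 667 of all 2643 tested probes rose. The median change of the 8 lay at the 90.45th percentile of random lists matched on level. With only 8 of 125 genes tested, the rises do not stand for the whole photosynthetic apparatus. Of the 6 rises 4 (PRK, PSBY, PSAN and LHCB1.5) also passed with the replicate number as a block and with consecutive replicates averaged, while those of CHLM and CHLP did not. The strongest rise was that of PRK (AT1G32060), the phosphoribulokinase of the Calvin-Benson cycle, at 4.38-fold (log2 change 2.13, SE 0.12, n = 6 each, limma, Benjamini-Hochberg adjusted p = 2.67e-08). PSBY (AT1G67740), a small photosystem II protein, rose 2.80-fold and PSAN (AT5G64040), a lumenal subunit of photosystem I itself, rose 2.25-fold. LHCB1.5 (AT2G34420), a light-harvesting protein of photosystem II, rose 1.80-fold, although its probe may also bind transcripts of the closely related LHCB1 genes. PSBW (AT2G30570), another small photosystem II subunit, was lower by 1.66-fold.

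The rises of PRK, PSBY, PSAN and LHCB1.5 also stood in the deposited intensities, before the normalization used here. The PRK intensity was 1.59 ± 0.14 in WT and 6.96 ± 0.58 in psah2, that of PSAN 4.33 ± 0.70 and 11.7 ± 0.9, that of PSBY 2.15 ± 0.38 and 6.29 ± 1.03, and that of LHCB1.5 12.2 ± 2.8 and 34.9 ± 5.9 (SD, n = 6 each). Centring on the lower psah2 medians raises all psah2 values against WT. The log2 changes were then 3.55 for PRK, 2.97 for PSBY, 2.88 for PSAN and 2.96 for LHCB1.5, which adds no support beyond the deposited values. PSBW was at 45.4 ± 1.3 in WT and 40.4 ± 3.0 in psah2, and its direction turned to a log2 change of 1.25 when arrays were only centred on their medians, and did not pass the test as deposited (adjusted p = 0.0918). Smaller rises were called for the chlorophyll synthesis genes CHLM (AT4G25080), the Mg-protoporphyrin IX methyltransferase, at 1.36-fold (adjusted p = 0.0269), and CHLP (AT1G74470), the geranylgeranyl reductase, at a log2 change of 0.26 (SE 0.10, adjusted p = 0.0356). Neither call held with the replicate number as a block (adjusted p = 0.0677 for CHLM and 0.0577 for CHLP) or with consecutive replicates averaged (0.170 and 0.227). CHLM had the opposite direction in the values as deposited, at a log2 change of -0.92. PSB27 (AT1G03600), a photosystem II assembly factor, had a log2 change of 0.43 with an SE of 0.50 and an adjusted p of 0.46.

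These 8 genes came from lists fixed before the data were examined, which were merged only afterwards, because no list alone had 5 tested members. Adjusted over the list alone, the same counts of 6 higher and 1 lower were obtained. The median log2 change of the merged list was 0.65 against -0.26 over all tested probes (camera with a preset correlation, adjusted p = 0.0323 over 4 lists). With an estimated correlation the call was lost (adjusted p = 0.11). For a change in 1 direction fry, which does not compare the list with other probes, gave an adjusted p of 1.33e-08. The call was also lost with consecutive replicates averaged (adjusted p = 0.0508), cyclic loess (0.0624) and array weights (0.0591), and without psah2 replicate 3 (adjusted p = 0.0518) or without psah2 replicate 4 (adjusted p = 0.0636).

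Of the other fixed lists, the plastid ribosomal proteins had 3 tested members, of which 2 rose and 1 fell, over all probes and adjusted over the list alone. RPL17 (AT3G54210) rose 4.14-fold and RPL5 (AT4G01310) 2.07-fold, while RPL29 (AT5G65220) was lower by 2.35-fold (limma, adjusted p = 2.15e-09, 1.43e-05 and 2.24e-06). With median-centred arrays RPL29 had a log2 change of -0.21 and did not pass the test (adjusted p = 0.170). RPL17 had a log2 change of 1.28 and RPL5 of -0.13 in the values as deposited, where the RPL5 intensity was 0.431 ± 0.060 in WT and 0.404 ± 0.114 in psah2 (SD, n = 6 each). FATB (AT1G08510), a plastid acyl-ACP thioesterase, rose 3.72-fold at intensities near 0.09 in both groups (adjusted p = 0.00558), and this turned to a log2 change of -0.21 in the values as deposited and did not pass the test with median-centred arrays (adjusted p = 0.0979). NTRC (AT2G41680), a plastid thioredoxin reductase, had a log2 change of 0.01 with an SE of 0.11 after normalization, but of -1.56 as deposited, at intensities of 0.339 ± 0.039 in WT and 0.116 ± 0.022 in psah2 (SD, n = 6 each). SBPASE (AT3G55800), a Calvin-Benson cycle enzyme that green tissue uses, was listed at 0 on all 6 WT and on 4 psah2 arrays, so that its probe gave no usable level. Markers of roots, non-green plastids and seeds had no probe in the annotation used here.

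**Figure D2:**
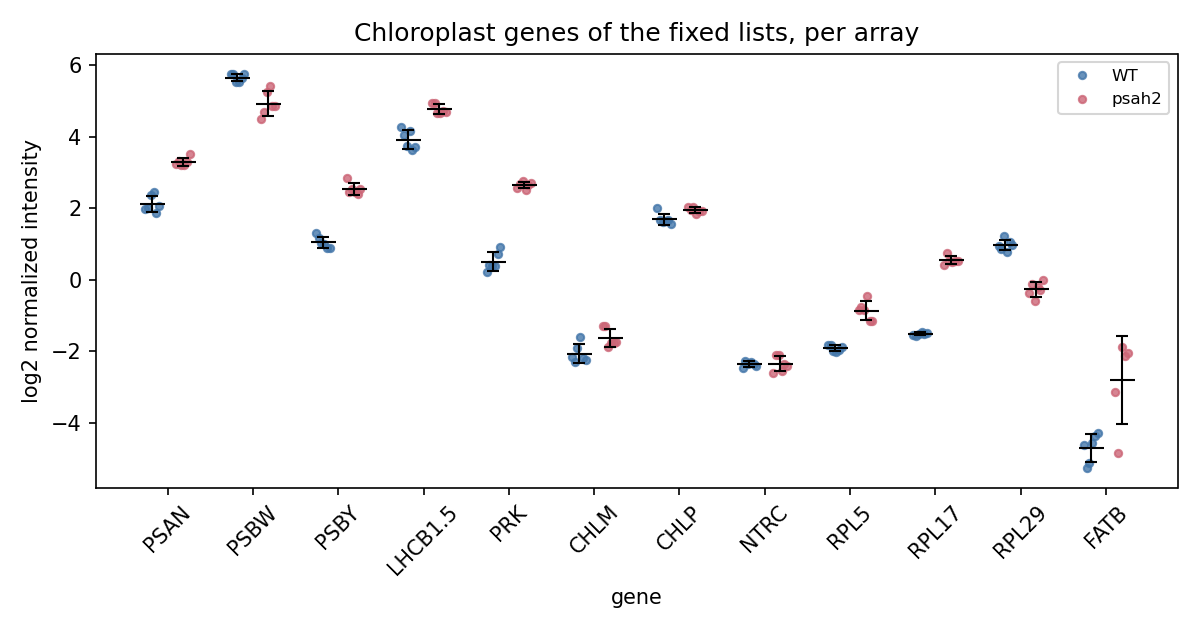
Log2 normalized intensity of 12 chloroplast genes from the fixed lists; points are single arrays (WT blue, psah2 red), the wide tick is the group mean and the bars are the SD. PSAN, PSBY, LHCB1.5, PRK and RPL17 are higher in psah2 on every array, PSBW and RPL29 are lower, and NTRC overlaps.

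Among all probes that name a single gene, 110 were higher and 217 lower in psah2, of 523 tested. The largest falls included several bright probes. AT4G31530 fell from an intensity of 54.3 ± 8.7 in WT to 7.85 ± 2.11 in psah2, which was 9.07-fold lower after normalization. AT2G27290 fell from 39.6 ± 2.4 to 6.84 ± 0.22 and was 7.14-fold lower, AT3G52070 from 3.72 ± 0.76 to 0.325 ± 0.060 and was 7.99-fold lower, and AT4G39690, the mitochondrial cristae protein MIC60, from 2.26 ± 0.19 to 0.175 ± 0.067 and was 8.36-fold lower (SD, n = 6 each; limma, adjusted p from 1.08e-09 to 1.14e-07). Centring on the lower psah2 medians raises all psah2 values, and the falls were then smaller. The log2 changes were -1.41 for AT4G31530, -1.11 for AT2G27290, -2.09 for AT3G52070 and -2.36 for AT4G39690. The other 6 of the 10 largest falls were at WT intensities under 1. They were AT4G23110, AT1G79220, a member of the mTERF family of organelle gene regulators (7.74-fold on the 4 psah2 arrays above 0), AT2G32040, a plastid folate transporter (7.57-fold), AT1G02020, AT4G20820, a berberine bridge enzyme-like protein (6.59-fold), and AT1G03810 (6.51-fold). With values at 0 set to a floor AT1G79220 had a log2 change of -3.91 instead of -2.95. As deposited these 6 falls were larger, with log2 changes from -4.37 for AT2G32040 to -5.12 for AT4G23110. The median over all tested probes was then -1.64, so the larger size adds no support. For AT1G02020 the fitted 7.42-fold fall varied with single arrays, from a log2 change of -2.31 without psah2 replicate 2 to -3.52 without psah2 replicate 4; its groups overlapped and psah2 replicate 6 was at 0. For AT4G23110 the size of the fitted 10.4-fold fall (adjusted p = 0.0265) rested on psah2 replicate 5, nearly at 0, without which the log2 change went from -3.37 to -1.94 (adjusted p = 6.26e-05); psah2 replicate 6 was at 0. Its call was lost with the replicate number as a block (adjusted p = 0.0532), averaged replicates (0.108) and cyclic loess (0.0798).

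The largest rises were found at lower intensities. AT3G47650, a DnaJ-type zinc finger protein, rose from an intensity of 0.926 ± 0.170 in WT to 3.87 ± 0.51 in psah2, a 5.41-fold change after normalization. FTRC (AT2G04700), the catalytic subunit of ferredoxin-thioredoxin reductase, which passes electrons from photosystem I to thioredoxins, rose 6.78-fold after normalization (limma, adjusted p = 1.08e-09). The deposited FTRC intensity rose less, from 0.180 ± 0.021 in WT to 0.442 ± 0.022 in psah2 (SD, n = 6 each). AT1G51080 rose 11.3-fold, TPP2 (AT4G20850), a tripeptidyl peptidase, 8.34-fold, AT2G21530 8.23-fold, AT3G25410, of the bile acid:sodium symporter family, 6.86-fold, and AT3G02030 5.69-fold. As deposited these rises were smaller, with log2 changes of 1.89 for AT1G51080, 0.88 for TPP2 (adjusted p = 0.0388), 1.69 for AT2G21530, 1.47 for AT3G25410 and 1.43 for AT3G02030. AT1G44920 was fitted at 6.60-fold, but it was at 0 on psah2 replicates 2 and 4, and its call was lost with values at 0 set to a floor (adjusted p = 0.107) and as deposited (log2 change 0.73, adjusted p = 0.288). For AT3G56010 the fitted log2 change of 5.90 rested on WT intensities of at most 0.0187, with 2 WT arrays at 0, so its size is uncertain. For AT5G06410, a co-chaperone of iron-sulfur cluster assembly, the log2 change of 2.91 (adjusted p = 0.0474) rested on psah2 replicate 3, at an intensity of 16.5, while psah2 replicates 1 and 2 were at 0. The AT5G06410 call was lost with the replicate number as a block (adjusted p = 0.146), averaged replicates (0.112), median-centred arrays (0.0942), cyclic loess (0.0748), a floor (0.434) and as deposited (0.339).

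Over all probes, 1625 of 2643 tested, or 61.5%, differed between psah2 and WT at an adjusted p below 0.05 (limma, Benjamini-Hochberg), with 667 higher and 958 lower in psah2. At a change of at least 1.5-fold, 588 were higher and 854 lower. The values of the groups did not overlap for 44.2% of the tested probes. With the values as deposited, whose median log2 change was -1.64, 251 probes were higher and 2049 lower, so that the higher share of the calls was 10.9% and not 41.0%. Each of these changes is therefore a change relative to the other probes of the array, and array set and genotype were not separated in the labels.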

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

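All tests in this part were run on groups of 6 arrays with a gap test, which chance passes in about 1 of 20 groups. Of 88 groups tested, 7 held an array apart from the other 5. In WT, replicate 6 was above the others for AT2G27290 (gap over range 0.965, log2 intensity 5.63 against a mean of 5.44), and replicate 1 for CHLP (0.760, against a mean of 1.63). In psah2, replicate 1 was below the others for AT4G31530 (0.626, 1.88 against 2.90) and above them for PSBY (0.653, 2.83 against 2.47). In psah2, replicate 6 was above the others for PSAN (0.644, 3.51 against 3.25), replicate 2 for RPL17 (0.635, 0.75 against 0.50), and replicate 3 was below them for AT3G46950 (0.686, -2.72 against -2.19). For AT2G27290 the gap was absent from the deposited intensities, where WT replicate 6 was at 39.6 and replicate 4 highest at 43.8; it arose in quantile normalization.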

How the results depend on the processing

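The count of higher probes was 667 and that of lower probes 958; both stayed within 1.5 times under every alternative except the values as deposited, which gave 251 and 2049. Of the 1625 called probes, 1197 kept call and direction as deposited and 333 turned direction; with median-centred arrays 1268 kept them and 112 turned, and with cyclic loess 1335 and 2. In those values CHLM (-0.92), RPL5 (-0.13), FATB (-0.21), FBN5 (-0.83), FBN2 (-1.23), CCS (-1.28) and SRX (-1.16) turned sign in log2 change, by construction, since the median of all probes was then -1.64. PSBW, at -0.17 as deposited, turned to 1.25 with median-centred arrays. This was also by construction, since centring on the lower psah2 medians raises all psah2 values. With the replicate number as a block, 654 probes were higher and 938 lower. Same-numbered WT and psah2 arrays resembled each other, as all 12 arrays correlated best with their own number. The residual correlation of same-numbered arrays ranged from 0.05 to 0.16 and exceeded 0.1 for 5 of 6 numbers, against at most 0.06 with another number. The main fit, fixed beforehand because the labels state no block, leaves this resemblance out. The block takes it in, as a fixed term or, in another alternative, as a random one. Among named genes the fixed block ended 4 calls (CHLM, CHLP, AT4G23110 and AT5G06410). With the random block, 687 probes were higher and 996 lower. It kept these 4 calls (limma, adjusted p = 0.0230, 0.0274, 0.0217 and 0.0429). Averaging consecutive replicates, 3 against 3, gave 545 and 730 of 2824 tested probes, with at least 2 averaged values in each group. The photosynthesis list's median of 0.65 ended its call with an estimated correlation (adjusted p = 0.11) and with averaged replicates (0.65, 0.0508), cyclic loess (0.83, 0.0624) and array weights (0.60, 0.0591); leaving out 1 array gave 0.59 to 0.78. As deposited the list's median was 0.88 (camera, adjusted p = 3.31e-06). With median-centred arrays it was 2.31 (4.93e-09, LHCB1.5 at 2.96, PSAN at 2.88), where centring on the lower psah2 medians raises all psah2 values. Values near 0 limit the dim probes: setting them to a floor ended 3 calls of named genes.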

Other observations

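The tests of this part were chosen after the data were seen, except the count over other splits of the samples. Gene groups written down after the probe names were known moved in different directions. Of 8 mTERF proteins, regulators of organelle gene expression, 6 were lower and 1 higher in psah2. AT3G46950 was 2.67-fold and AT1G62150 1.75-fold lower, while AT5G55580 was 1.86-fold higher; AT1G62150 lost its call when arrays were only centred on their medians. Of 15 tested pentatricopeptide repeat proteins, which bind organelle RNAs, 7 were lower, such as AT2G19280 (2.58-fold), AT2G17670 (2.09-fold), AT4G21170 (1.91-fold) and AT4G04370 (1.87-fold), and 4 were higher, AT3G22150 the most (2.90-fold after normalization, although its deposited mean intensity was lower in psah2, at 0.0925 against 0.114). AT4G21170 lost its call with median-centred arrays (adjusted p = 0.162) and AT2G17670 with values at 0 set to a floor (adjusted p = 0.112), and AT2G19280 went from a log2 change of -1.37 to -0.24 with median-centred arrays. Neither list stood apart from the other probes in camera (adjusted p = 0.38 for each, and 0.47 and 0.76 with an estimated correlation). For a change in 1 direction fry, which does not compare the members with other probes, gave adjusted p of 0.00131 and 4.49e-05. As 61.5% of all tested probes were called, passing fry does not set a list apart.

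Of 5 fibrillins, lipid-associated proteins of plastoglobules and thylakoids, 3 were higher, FBN6 (3.65-fold), FBN5 (1.84-fold) and FBN2 (1.38-fold), and FBN8 was 2.99-fold lower, with FBN10 below the threshold only when adjusted over the list alone (camera adjusted p = 0.38, 0.47 with an estimated correlation; fry adjusted p = 0.00078). FBN5 and FBN2 turned sign in the values as deposited, where FBN6 had a log2 change of 0.15 and did not pass the test (adjusted p = 0.517). FBN2 also lost its call with median-centred arrays (adjusted p = 0.201) and with consecutive replicates averaged (adjusted p = 0.0853), and FBN8 with cyclic loess (adjusted p = 0.0585). Of 4 tested plastid redox proteins 3 were higher, FTRC, the copper chaperone CCS (1.63-fold) and the sulfiredoxin SRX (1.42-fold), of which CCS and SRX turned sign in the values as deposited and lost their calls with median-centred arrays (adjusted p = 0.553 and 0.196), SRX also with consecutive replicates averaged (adjusted p = 0.131). NdhS, a subunit of the thylakoid NDH complex that accepts electrons from ferredoxin, was 3.10-fold lower, from a deposited intensity of 6.11 ± 0.79 in WT to 2.13 ± 0.31 in psah2 (SD, n = 6 each), but lost its call with median-centred arrays (log2 change -0.10, adjusted p = 0.508). The other 2 tested genes of that group, CRR21 and PIFI, had log2 changes of 0.08 and 0.13 and did not pass the test. There were 66 probes at 0 on all psah2 arrays and above 0 on all WT arrays, against 1 with the reverse, beside the lower brightness of the psah2 arrays.

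The extent of the difference, 1625 of 2643 probes, was reached only by the real 1 of 100 splits into 6 and 6. The highest of the others called 2. Mixed splits count the difference between the groups as spread within groups, so few calls were bound to follow. The splits also treat the arrays as independent, although same-numbered and consecutive arrays resembled each other. They show that the difference follows the group labels, but cannot exclude chance between fewer independent samples or an effect of the array set. Cyclic loess removes a brightness difference that follows the level, and 1335 of the 1625 probes kept their call and direction after it. It was run on the deposited values in place of quantile normalization, which itself evens out the arrays. Much of this agreement was thus bound to follow. As deposited, 1197 kept call and direction and 333 turned. For the probes still called after cyclic loess, a trend that it removes is argued against as the whole cause. A set of filters or hybridisations particular to each group may still account for part of the difference. Changes of 2 probes annotated with the same genes correlated with r = 0.255 over 47 such pairs (Spearman's rho 0.258, permutation p = 0.0823, across probes). By the bound set, after a first such correlation had been seen, this was within chance, as differences between spots or filters would leave it. With 46 of the pairs annotated with several genes, the probes may also not measure the same transcripts. The genotype is the biological explanation that the design names, and the labels do not allow it to be separated from the array set.

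The rise of the photosynthesis genes may be linked to their brightness. The list's median log2 change of 0.65 lay at the 90.45th percentile of 10000 random lists of 8 probes matched on level. This was below their upper limit of 0.98, so that about 1 in 10 lists matched in this way shifted as far. The match was coarse, by 10 bins of level, while a member such as PSBW was at the 99.7th percentile of level. The bright end of the scale is also where psah2 arrays reach the top. PRK and PSBY, with the largest changes of the list, were at the 96.6th and 97.1st percentile of level. Cyclic loess was run on the deposited values in place of quantile normalization. The log2 changes were then 2.06 for PRK and 1.43 for PSBY, against 2.13 and 1.49 with quantile normalization. Both normalizations even out brightness, so their likeness says little. That rises remained after cyclic loess argues only against a trend that it removes as the whole cause of these 2 rises. For the list as a set the call ended with cyclic loess (camera, adjusted p = 0.0624). The list's median log2 change was 0.88 as deposited, against -1.64 over all probes. After cyclic loess it was 0.83 against -0.12, and with quantile normalization 0.65 against -0.26. The list thus stood less far from the other probes after either normalization than as deposited. The lost call alone does not decide on brightness, which stays open for the list by the lists matched on level.

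Arrays with consecutive numbers resembled each other. The mean residual correlation within the pairs 1-2, 3-4 and 5-6 was 0.27 in WT and 0.02 in psah2, against at most -0.01 and -0.10 for the other 14 pairings of each group, and of the 225 combinations of pairings only 1, the real 1, was as high. This is consistent with consecutive numbers sharing an RNA, a filter or a hybridisation, which these data do not tell apart, and the 6 arrays of a group may then stand for 3 independent samples. In that case 545 probes were higher and 730 lower in psah2, of 2824 tested with at least 2 averaged values in each group. The main fit tested 2643 probes, with at least 4 values in each group.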
